A study of Homo sapiens with 6 samples.

How the data were processed

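RNA-seq libraries from T24, an established human bladder cancer cell line, were analysed from the table the authors deposited. The labels name 3 control libraries with no treatment and 3 libraries from cells given 3.84 µM Caba-780 for 24 h. Each library was assigned to its group and replicate number from its title. Per the labels' protocols, total RNA was extracted and libraries were made with the NEBNext Ultra RNA kit. The labels do not say that the replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical.

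Per the submitters' processing notes, fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3, DESeq2 1.20.0 and the hg38 build were used. The settings of these tools, the strand setting and the annotation release are not given in the sources used here. The table the authors deposited lists 23619 genes. Its 6 library columns hold a normalized signal, which is the count of reads per gene divided by 1 size factor per library. Every value was a whole multiple of 1 unit per library at a tolerance of 1e-06, and 100% of values gave whole reads when that unit was removed. The deposited group columns hold the authors' means of this signal and differed from means of the library columns by at most 4.1e-10. The deposited log2 fold change, p-value and adjusted p-value columns come from the authors' own comparison. In that table the adjusted p-value was 1 in 7787 rows, and 2 rows had no p-value. The deposited gene length column (unit other) gives bases per gene. Gene names written as dates in 25 rows were replaced from a gene name table by gene ID, and 174 rows that share a symbol were kept apart by ID. Start and end equalled those of GENCODE v29 (GRCh38) in 23616 of the 23619 rows, and in all 29 named genes.

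The reads recovered in genes ranged from 14591234 to 15983035 per library. A floor of 3 reads corresponded to 0.188 to 0.206 CPM. Such floors cover counting error only, because PCR copies are not independent molecules.

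The comparison of Caba-780 with control used limma 3.58.1 in R 4.3.3 on log2(value + 1) of the deposited normalized signal, with a mean-variance trend and robust moderation. Genes were kept with at least 10 normalized counts in at least 3 libraries. Tests were two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The pseudocount by itself shrinks the fold of low genes, while a gene with 0 or few reads in 1 library of a group can show a larger fold on this scale than the group means give. The test planned before the data were examined was the quasi-likelihood test of edgeR with TMM scaling for a table of raw counts, with this limma test in its place for normalized values. The trend and robust options and the filter were set after the values and the quality of the libraries had been seen, and before any test result. The quasi-likelihood test of edgeR 4.0.16, the Wald test of DESeq2 1.42.0 and limma-voom were run on the recovered whole reads as alternatives.

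The 30 gene lists, the rule for named genes and the main alternatives were fixed before the data were examined. Named genes were the 7 with the largest rise and the 7 with the largest fall among protein-coding genes with an adjusted p under 0.05, at least 5 CPM on average and no overlap between the groups. To these were added the 2 members with the lowest p of 4 lists always shown and of up to 6 other lists with the lowest camera p. Other genes named in the text were chosen after their values were seen. Lists with at least 5 tested genes were tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over the 27 lists tested. The call was repeated with an estimated correlation, and fry was run as another set test. Members were also adjusted over the list alone. The results of 1 of the 4 lists always shown, and of some single genes, are not reported here.

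Alternatives changed the scaling, the low-count filter, the pseudocount, the test, the threshold, the replicate number as a block and each library in turn. Library weights, TMM scaling in limma, other pseudocounts, correction for GC content and length, the edgeR test with TMM as applied to recovered reads, and settings combined with leaving out control replicate 3 were chosen after the data were seen. All pairs of libraries within a group differed by more than sampling noise, with chi-square per degree of freedom from 10.8 to 233, so no library was counted as a duplicate. This measure covers counting error only, so it cannot exclude that libraries are technical replicates.

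The fits were tested on simulated data with 200 changed genes among about as many genes as were tested. With 6 ordinary libraries and 13410 genes, limma recovered 70.2% of genes changed 1.5-fold, 97.0% at 2-fold and 100% at 4-fold, with 18 false calls. When control replicate 3 was drawn from few molecules (13400 genes), it recovered 32.8%, 83.6% and 92.4%, with 0 false calls. Leaving that library out (13320 genes) gave 46.3%, 92.5% and 100%, with 7 false calls. The simulation drew no bias in GC content or length, so these shares do not give the recovery in the real data. There, limma called 99 genes higher and 34 lower at 2-fold or more with 6 libraries, and 815 and 361 without control replicate 3. A simulated list of 30 genes raised 2-fold had a camera p of 1.17e-64, and 4 of 200 unchanged lists had a p under 0.05. Genes were drawn independently there, in 6 ordinary libraries, so false calls that come from correlation between genes could not appear.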

Results

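Gene expression was measured by RNA-seq in T24 human bladder cancer cells, with 3 control libraries, labelled as given no treatment, and 3 libraries from cells given 3.84 µM of the near-infrared fluorescence imaging drug Caba-780 for 24 h. The labels do not say whether the control cells received a vehicle. The study set out to compare the expression profiles of the control and treated groups, under a title that asks for the molecular mechanism of the drug. Reads in genes numbered 15785965, 15033139 and 14591234 in control replicates 1 to 3, and 15983035, 15287828 and 14649171 in Caba-780 replicates 1 to 3. Levels below are normalized counts, the authors' read counts divided by a size factor, given as mean ± SD (n = 3 per group). Changes are Caba-780 over control on the log2(value + 1) scale with the standard error (SE) of limma, and positions are on GRCh38.

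Control replicate 3 stood apart from the other libraries. It had reads in 13627 genes, against 19467 to 20308 in the others, although its total was similar. Only 638 of its genes held 1 to 9 reads, against 5636 to 6100 elsewhere. Among 1354 genes with 20 to 50 reads on average in control replicates 1 and 2, 35.9% had no read in control replicate 3. Its Pearson r across genes was 0.869 and 0.871 with the other controls, and 0.850 to 0.873 with the treated libraries. Between the other controls r was 0.986, and among treated libraries it was 0.983 to 0.989. Genes are not independent replicates, and these values describe the libraries only. Counts over all genes are therefore also given without control replicate 3, and counts adjusted over the list alone are those with 6 libraries.

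**Figure D1:**
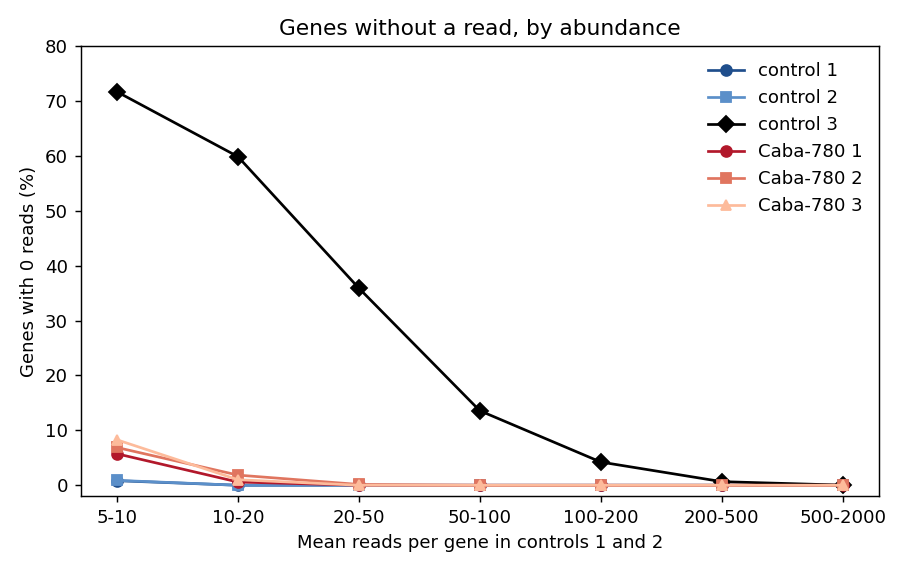
Share of genes with 0 reads (vertical axis, percent) in each of the 6 libraries, by the mean reads per gene in control replicates 1 and 2 (horizontal axis, reads), with 1 line per library. In genes of 10 to 20 reads, control replicate 3 had no read in 59.8%, and the other libraries in at most 1.85%.

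With Caba-780, the circadian repressor NR1D1 and the growth arrest gene GADD45A rose, as did 4 of 17 genes of NF-kB signalling and 4 of 23 genes of the stress response through the transcription factor ATF4. The orphan nuclear receptors NR4A2 and NR4A3 fell, as did 9 of 30 genes of mitosis, among them the mitotic kinases PLK1 and AURKA. The limma camera calls of these 3 lists were lost when the correlation was estimated (NF-kB adjusted p = 0.263, ATF4 adjusted p = 0.264 and mitosis adjusted p = 0.263 with an estimated correlation). Of 13847 genes tested, 103 were higher and 36 lower with limma (adjusted p under 0.05). Without control replicate 3, 2359 were higher and 2077 lower of 13708 tested, which included all 139 genes called with 6 libraries, in the same direction. DESeq2 on the recovered reads of all 6 libraries called 729 higher and 494 lower. Leaving out control replicate 1 left 1 gene called (NR1D1, higher), and leaving out control replicate 2 or any one of the 3 Caba-780 libraries left 0, with 1092 to 1948 genes at an unadjusted p under 0.05 in those 4 limma fits. Scaling by library totals without control replicate 3 changed the split to 2956 higher and 1330 lower, so that 69.0% of calls were higher against 53.2%. With all 6 libraries, the median log2 change of all tested genes was 0.10 with the deposited size factors, 0.23 with library totals and −0.01 with upper-quartile scaling. Without control replicate 3 it was −0.02 with the deposited size factors and 0.08 with library totals.

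The largest rise with 6 libraries was that of HSPA6 (ENSG00000173110, chromosome 1, 161524540 to 161526910), an inducible HSP70 chaperone, from 2.36 ± 2.60 to 245 ± 56.2, a change of 6.53 ± 0.73 (SE). Its reads were 2, 5 and 0 in the controls and 340, 205 and 241 in the treated libraries, and HSP70 genes have near-identical copies that can share reads. TRAF1 (ENSG00000056558, chromosome 9, 120902393 to 120929173), an adaptor of TNF receptors, rose from 117 ± 81.1 to 3156 ± 279, by 5.06 ± 0.61. ANKRD1 (ENSG00000148677, chromosome 10, 90912096 to 90921276), an ankyrin-repeat protein, rose from 29.1 ± 15.0 to 827 ± 128, by 4.89 ± 0.40. GADD45A (ENSG00000116717, chromosome 1, 67685061 to 67688338), induced by DNA damage and other stress, rose from 571 ± 311 to 9627 ± 737, by 4.28 ± 0.50. NR1D1 (ENSG00000126368, chromosome 17, 40092787 to 40100725), also called REV-ERB alpha, rose from 120 ± 28.1 to 2000 ± 278, by 4.06 ± 0.24. TNFAIP3 (ENSG00000118503, chromosome 6, 137867188 to 137883312), the NF-kB feedback inhibitor A20, rose from 169 ± 40.8 to 2623 ± 396, by 3.96 ± 0.24. PTX3 (ENSG00000163661, chromosome 3, 157436789 to 157443628), a secreted pattern recognition protein, rose from 26.2 ± 5.80 to 361 ± 73.9, by 3.74 ± 0.28. The limma adjusted p of these 7 genes ranged from 0.0118 (NR1D1, TNFAIP3) to 0.0332 (TRAF1), and HSPA6 missed the threshold with limma-voom (adjusted p = 0.0529). Without control replicate 3 the changes of HSPA6 (5.83 ± 0.33), TRAF1 (4.34 ± 0.17) and GADD45A (3.68 ± 0.13) were smaller, and that of ANKRD1 (4.53 ± 0.21) exceeded that of TRAF1. By the same rule without that library, the complement gene C3 (4.25) and the immediate early gene ARC (4.15) came before NR1D1 (3.91) and PTX3 (3.90), and TNFAIP3 and GADD45A were no longer among the 7 largest rises.

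The largest fall with 6 libraries was that of NR4A2 (ENSG00000153234, chromosome 2, 156324432 to 156342348), from 1526 ± 476 to 107 ± 18.6, a change of −3.79 ± 0.29 (SE). NR4A3 (ENSG00000119508, chromosome 9, 99821855 to 99866891), of the same receptor family, fell from 1190 ± 238 to 125 ± 25.5, with a change of −3.24 ± 0.25. EGR3 (ENSG00000179388, chromosome 8, 22687659 to 22693302), an immediate early transcription factor, fell from 226 ± 83.4 to 32.9 ± 7.46, with a change of −2.69 ± 0.38. PADI3 (ENSG00000142619, chromosome 1, 17249098 to 17284233), a peptidylarginine deiminase, fell from 327 ± 29.8 to 59.4 ± 4.02, with a change of −2.44 ± 0.21. KLHL14 (ENSG00000197705, chromosome 18, 32672671 to 32773062) fell from 142 ± 22.0 to 28.5 ± 5.17, with a change of −2.28 ± 0.29. PLK1 (ENSG00000166851, chromosome 16, 23677656 to 23690367), a kinase of mitotic entry and spindle assembly, fell from 2462 ± 828 to 513 ± 96.7, with a change of −2.21 ± 0.32. KIF20A (ENSG00000112984, chromosome 5, 138178719 to 138187715), a kinesin of cytokinesis, fell from 3837 ± 794 to 844 ± 57.4, with a change of −2.16 ± 0.21. The limma adjusted p of these 7 genes ranged from 0.0156 (NR4A2, NR4A3) to 0.0431 (PLK1), and the calls were lost for EGR3 with limma-voom (adjusted p = 0.0796) and for PLK1 with library totals alone (limma adjusted p = 0.0521). By the same rule without control replicate 3, PIF1, a helicase gene, fell most (−4.38), ahead of NR4A2 (−4.02), and NR4A1 (−3.52) fell more than NR4A3 (−3.09).

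**Figure D2:**
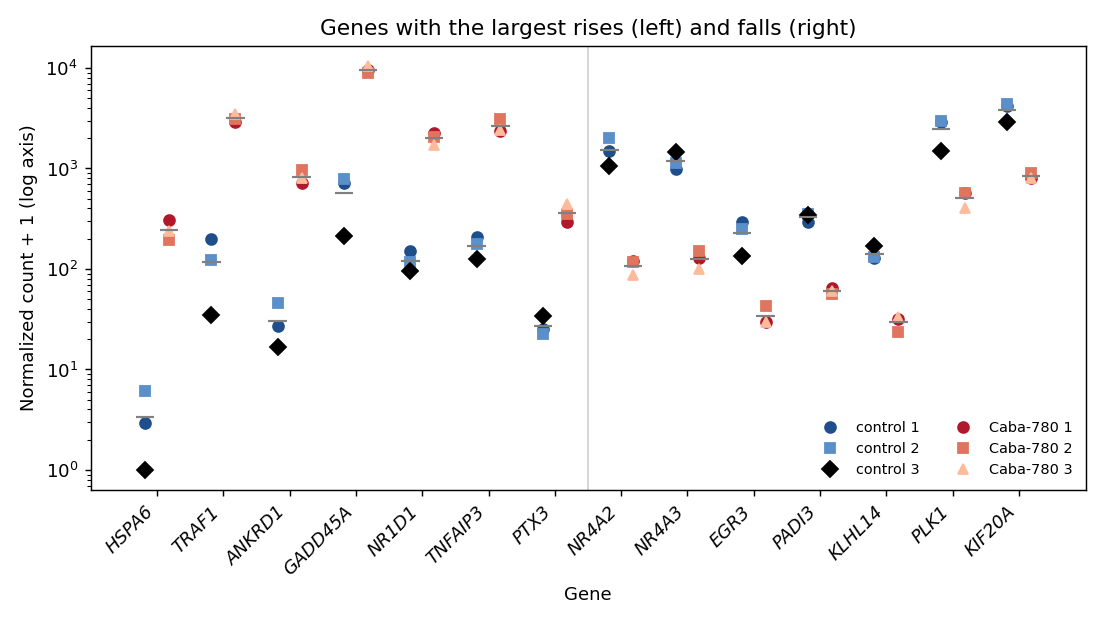
Normalized count + 1 (vertical log axis) of the 7 genes with the largest rises and the 7 with the largest falls (horizontal axis), with 1 point per library and grey lines for the mean of the 3 libraries of a group. By the rule that chose them, the groups do not overlap in any of the 14 genes. GADD45A lies between 213 and 779 normalized counts in the controls and between 8999 and 10438 with Caba-780.

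Of 30 genes of mitosis and G2/M tested, 9 fell and none rose, and 20 fell when adjusted over the list alone. Besides PLK1 and KIF20A, AURKA (chromosome 20, 56369389 to 56392337), a spindle pole kinase, fell from 2675 ± 218 to 836 ± 71.4, with a change of −1.68 ± 0.16. CCNB1, the cyclin that activates CDK1, fell by 2.13, and BUB1, a kinase of the spindle checkpoint, fell by 1.64. The list had a median log2 change of −0.96 and a limma camera adjusted p of 1.2e-18, which became an adjusted p = 0.263 with an estimated correlation. In the fit without control replicate 3, 23 of the 30 fell and none rose.

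Of 31 genes of DNA replication and S phase tested, CCNE1, CDC6 and ORC6 rose and none fell, and 10 rose when adjusted over the list alone. CCNE1 (chromosome 19, 29811898 to 29824308), the G1/S cyclin E1, rose from 354 ± 10.4 to 856 ± 60.4, by 1.27 ± 0.16. CDC6 (chromosome 17, 40287633 to 40304657), which loads the replicative helicase, rose from 1683 ± 207 to 3715 ± 44.0, by 1.15 ± 0.16. The list's median change was 0.47, with a limma camera adjusted p of 2.35e-06 and an adjusted p = 0.263 with an estimated correlation. When control replicate 3 was left out, 18 of the 31 rose and none fell.

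Of 10 genes tested in the list of replication-dependent histones, 2 fell and none rose, and 5 fell when adjusted over the list alone. HIST1H2AC (chromosome 6, 26124145 to 26139116), a core histone H2A, fell from 484 ± 82.7 to 168 ± 25.8, with a change of −1.52 ± 0.23. H1F0 (chromosome 22, 37805093 to 37807436), a linker histone made outside S phase and known from cells that have stopped dividing, fell from 332 ± 49.6 to 114 ± 22.7, with a change of −1.54 ± 0.24. It is thus not replication-dependent itself, although the counts and tests of the list include it, and HIST1H2AC was the only other member called with 6 libraries. The median was −1.33, with a limma camera adjusted p of 2.88e-06 and an adjusted p = 0.264 with an estimated correlation. With control replicate 3 left out, 7 of the 10 fell. The labels do not say whether RNA was poly(A) selected, which can change how much histone mRNA a library holds. These are therefore changes in counted reads, and may not stand for histone mRNA as a whole. Histone genes are alike in sequence, so counts of single members are uncertain, and H1F0 missed the threshold with edgeR under TMM scaling (adjusted p = 0.0534) but not under DESeq2 size factors (edgeR adjusted p = 0.0492) and both genes missed it with library totals alone in limma (adjusted p = 0.0578 for HIST1H2AC and 0.0640 for H1F0).

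Of 17 genes of NF-kB signalling and inflammatory cytokines tested, TNFAIP3, ICAM1, BIRC3 and NFKB1 rose and none fell, and 8 rose when adjusted over the list alone. NFKB1 (chromosome 4, 102501329 to 102617302), the p105/p50 subunit, rose from 1135 ± 47.1 to 3955 ± 205, by 1.80 ± 0.15. ICAM1, an adhesion molecule, rose by 3.09. The median change was 2.27, with a limma camera adjusted p of 1.19e-08 and an adjusted p = 0.263 with an estimated correlation. Without control replicate 3, 12 of the 17 rose and none fell, and the median was 1.66. The 8 further genes that then passed were the NF-kB subunits RELB (3.16) and NFKB2 (2.00), and the cytokines TNF (3.18), CXCL8 (2.82), CCL2 (1.66), CXCL3 (1.19), IL6 (1.02) and CXCL2 (0.57). CCL2 (10.8 to 17.0 normalized counts with Caba-780) and IL6 (32.3 to 59.4) were low and passed narrowly (limma adjusted p = 0.0418 and 0.0466). CCL20 (0.88), LIF (0.33), NFKBIA (0.10), CXCL1 (0.03) and PTGS2 (−0.11) did not pass.

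Among 24 apoptosis regulators, BIRC3 rose and none fell, and 5 rose and 3 fell when adjusted over the list alone. BIRC3 (chromosome 11, 102317450 to 102339403), an inhibitor of apoptosis and NF-kB target, rose from 1027 ± 385 to 4965 ± 920, by 2.32 ± 0.30. BMF (chromosome 15, 40087890 to 40108892), a pro-apoptotic BH3-only protein, was 582 ± 106 in controls and 234 ± 31.3 with Caba-780, a change of −1.31 ± 0.22 that missed the threshold (limma adjusted p = 0.0613). The list as a whole had no camera call, with a limma camera adjusted p of 0.426. With fry it was called upward with 6 libraries (fry adjusted p = 0.0452) and not without control replicate 3 (0.0553). In the fit without control replicate 3, 7 rose, among them BIRC2, BCL2 and the BH3-only genes BCL2L11 and PMAIP1, and 4 fell, which were BMF, MCL1, CASP6 and CASP9.

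Of 23 genes of the ATF4 integrated stress response tested, SESN2, PHGDH, CEBPG and TRIB3 rose and none fell, and 17 rose when adjusted over the list alone. SESN2 (chromosome 1, 28259527 to 28282491), a stress-induced inhibitor of mTORC1, rose from 169 ± 57.7 to 993 ± 107, by 2.60 ± 0.30. TRIB3 (chromosome 20, 362835 to 397559), a pseudokinase induced by ATF4, rose from 472 ± 27.7 to 1393 ± 239, by 1.55 ± 0.20. The median change was 1.27, with a limma camera adjusted p of 3.17e-10 and an adjusted p = 0.264 with an estimated correlation. When control replicate 3 was left out, 17 of the 23 rose and none fell, among them CHAC1 (2.74), PPP1R15A (1.74) and DDIT3 (1.46), while ATF4 itself changed by 0.30 ± 0.14 and did not pass (limma adjusted p = 0.102). Of 20 genes of the unfolded protein response, 0 were called with 6 libraries, and 4 rose and 4 fell without control replicate 3. ERN1 (1.30) was among those that rose, and the chaperone HSP90B1 (−0.47) among those that fell.

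Of 22 genes of AP-1 and the immediate early response tested, EGR3 and SPRY2 fell and none rose, and 11 fell when adjusted over the list alone. SPRY2 (chromosome 13, 80335976 to 80340951), a feedback inhibitor of receptor tyrosine kinase signalling, fell from 3093 ± 307 to 1281 ± 76.7, with a change of −1.27 ± 0.16. The median change was −0.78, with a limma camera adjusted p of 3.44e-07 and an adjusted p = 0.264 with an estimated correlation. Without control replicate 3, 16 of the 22 fell, among them EGR2 (−3.48), FOSB (−2.11), MYC (−1.46) and DUSP6 (−1.16), and only JUN rose (0.39).

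None of 30 cytosolic ribosomal protein genes passed with 6 libraries, over all genes or adjusted over the list alone, and the median was −0.30. RPL27 (chromosome 17, 42998273 to 43002959) was 7807 ± 974 in controls and 5048 ± 308 with Caba-780 (−0.62 ± 0.16), and RPL5 (chromosome 1, 92831983 to 92841924) was 11580 ± 1354 and 8180 ± 511 (−0.50 ± 0.16). The limma camera adjusted p of this list was 4.00e-05, with an adjusted p = 0.535 with an estimated correlation. In the fit without control replicate 3, 19 of the 30 fell and none rose. None of 29 nuclear-encoded respiratory chain genes passed with 6 libraries either way, with a median of −0.33, a limma camera adjusted p of 2.73e-05 and an adjusted p = 0.337 with an estimated correlation. In that list COX7C (chromosome 5, 86617904 to 86620962) was 3366 ± 742 in controls and 1819 ± 244 with Caba-780 (−0.87 ± 0.22), and NDUFB3 (chromosome 2, 201071433 to 201085750) was 596 ± 203 and 302 ± 63.7 (−0.94 ± 0.30). When control replicate 3 was left out, 14 of the 29 fell and none rose. Ribosomal protein genes have many processed pseudogenes that can share reads.

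Of 26 genes of hypoxia and glycolysis, 0 passed with 6 libraries and 1 fell when adjusted over the list alone, with a limma camera adjusted p of 0.0241 downward and an adjusted p = 0.473 with an estimated correlation. With control replicate 3 left out, 10 of 25 fell, among them LDHA (−0.76), PGK1 (−0.74) and GAPDH (−0.55), and none rose. ALDOC (−2.07 with 6 libraries, not called) was then not tested, because its Caba-780 libraries (3.58 to 7.85 normalized counts) lay under the filter. The limma camera call of this list was lost without control replicate 1 (adjusted p = 0.232), control replicate 2 (0.157) or Caba-780 replicate 2 (0.0754), and with a stricter filter of 5 CPM (0.121). Of 22 cholesterol synthesis genes, 0 passed with 6 libraries either way, with a limma camera adjusted p of 0.0303 downward and an adjusted p = 0.264 with an estimated correlation. Without control replicate 3, 6 fell, among them STARD4 (−0.55) and FDFT1 (−0.47). Its limma camera call was lost without control replicate 1 (adjusted p = 0.0714), control replicate 2 (0.126) or Caba-780 replicate 2 (0.119), with library totals alone (0.0552) and with a stricter filter of 5 CPM (0.0605). Of 13 mitochondrially encoded mRNAs, 0 passed with 6 libraries either way, with a limma camera adjusted p of 0.0344 downward and an adjusted p = 0.755 with an estimated correlation. That call was lost without control replicate 3 (limma camera adjusted p = 0.945), where MT-ND6 rose (0.87) and MT-CO1 fell (−0.87), and without Caba-780 replicate 3 (0.394).

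**Figure D3:**
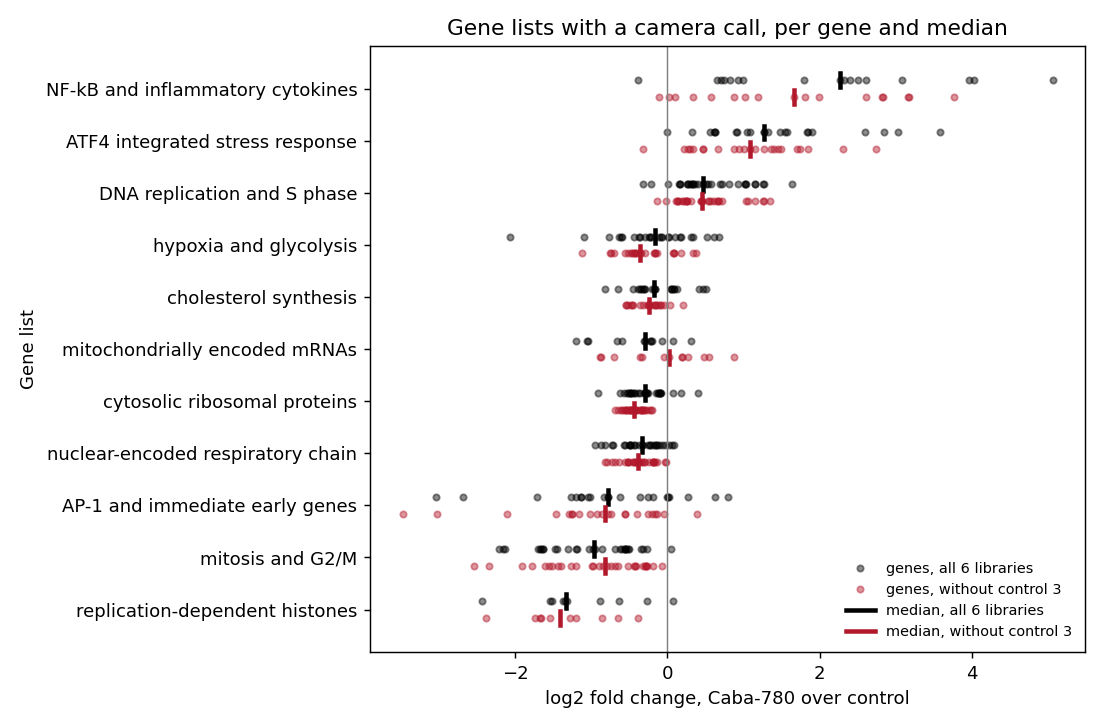
Log2 fold change of Caba-780 over control (horizontal axis) for the genes of 11 of the 12 lists with a limma camera call (vertical axis), with 1 point per gene and a bar at the median, in black with all 6 libraries and in red without control replicate 3. The mitosis list has medians of −0.96 and −0.82, and the NF-kB list 2.27 and 1.66, while the median of the mitochondrially encoded mRNAs is −0.29 with all 6 libraries and 0.02 without control replicate 3.

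The interferon response, DNA repair and tubulin lists had no limma camera call in the main setting with 6 libraries, and were called without control replicate 3. With library weights, where control replicate 3 weighed 0.046, limma camera called them with 6 libraries (adjusted p = 0.0174, 0.0132 and 0.00980). With 6 libraries, fry also called the interferon list (fry adjusted p = 0.00811). GC and length correction gave a limma camera call of the tubulin list (adjusted p = 0.0348). Of 20 interferon response genes, 0 passed with 6 libraries either way (limma camera adjusted p = 0.0736), and 10 rose and 1 fell without control replicate 3, with IRF1 (1.06) and IFIH1 (0.93) higher and IFIT1 (−1.15) lower. The limma camera adjusted p was then 0.0143, with an adjusted p = 0.374 with an estimated correlation, and the list was also called without Caba-780 replicate 1 (0.0390). Of 23 DNA repair genes, 0 passed with 6 libraries either way, and without control replicate 3, 10 rose, among them EXO1 (1.21) and BRCA2 (0.88), and XRCC6 fell (−0.58), with a limma camera adjusted p of 0.00875 and an adjusted p = 0.395 with an estimated correlation. Of 18 tubulins and microtubule proteins, 0 passed with 6 libraries either way, and without control replicate 3, TUBB3 rose (0.72) and 7 fell, among them TUBA1B (−0.65) and TUBB (−0.47), with a limma camera adjusted p of 0.0125 and an adjusted p = 0.395 with an estimated correlation.

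The other lists reported here had no limma camera call in the main setting, with or without control replicate 3. With fry, the ferroptosis and iron list was called upward with 6 libraries (fry adjusted p = 0.0452) and without control replicate 3 (0.00414). Its median log2 change was only 0.004 and 0.047 in these fits, with limma camera adjusted p of 0.705 and 0.397. Its members CHAC1 and SLC7A11, which rose without control replicate 3, also belong to the ATF4 list. Fatty acid synthesis was called downward by limma camera with 6 libraries under GC and length correction (adjusted p = 0.0185). With 6 libraries, 0 members passed in the lists of heat shock (16 tested), NRF2 antioxidant genes (18), receptor tyrosine kinases and angiogenesis (15), fatty acid synthesis (11) and luminal urothelial markers (7), over all genes or adjusted over the list alone. Adjusted over the list alone, 2 of 16 ferroptosis and iron genes rose, 1 of 22 autophagy and lysosome genes rose, 1 of 20 unfolded protein response genes rose, 1 of 12 drug efflux and metabolism genes rose and 1 fell, and 3 of 24 EMT and extracellular matrix genes rose and 2 fell, and none of these lists had a gene that passed over all genes. Of 20 ribosome biogenesis genes, RRP12 rose (1.48) over all genes and over the list alone. In the fit without control replicate 3, 3 heat shock genes rose, with BAG3 (0.57) among them, and 7 fell, with HSPA8 (−0.42) and HSP90AA1 (−0.40) among them. Of the NRF2 list 5 rose and 2 fell, of the ferroptosis list 4 rose and 2 fell, of the receptor tyrosine kinase list 4 rose and 2 fell, and of the EMT list 7 rose and 4 fell. Of the fatty acid list 3 fell, of the autophagy list 2 rose (SQSTM1 by 1.27 and MAP1LC3B by 0.90) and 3 fell, and of the ribosome biogenesis list 3 rose and 3 fell. Of 11 drug efflux genes 3 rose, with ABCB1 (1.44) among them, and 3 fell. With 6 libraries ABCB1, the efflux pump P-glycoprotein, was 133 ± 46.8 in controls and 433 ± 11.2 with Caba-780 and did not pass (limma adjusted p = 0.0709).

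Markers of urothelial type and of other cell types were few. When control replicate 3 was left out, FOXA1 (0.69) rose and UPK1B (−0.57) and ELF3 (−1.51) fell among 7 luminal markers. Of the basal and squamous markers only CD44 and ITGB4 could be tested. Neither passed over all genes with 6 libraries, 1 rose when adjusted over the list alone, and both rose without control replicate 3 (CD44 by 0.81 and ITGB4 by 0.65). Of the leukocyte markers only ITGAM could be tested, with 6.60 ± 6.33 normalized counts in controls and 48.9 ± 2.83 with Caba-780. With 1 gene tested, adjustment over the list alone changes nothing, so ITGAM passed there only at an unadjusted limma p under 0.05. It did not pass over all genes with 6 libraries (limma adjusted p = 0.196), and rose by 2.24 without control replicate 3. Of the fibroblast and endothelial markers only ACTA2 and MYH11 could be tested, and neither passed with or without control replicate 3.

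In the authors' deposited table, 556 genes were higher and 284 lower at an adjusted p under 0.05, of which 439 and 209 also changed at least 2-fold. All 139 genes called here with 6 libraries were among these 840 genes of the authors' deposited table. Of the 840 genes in the authors' deposited table, 808 were also called here without control replicate 3, all 808 in the same direction.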

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

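Library weights, TMM scaling in limma, edgeR with TMM (planned for raw counts) on the recovered reads, other pseudocounts, GC and length correction and settings combined with leaving out control replicate 3 were chosen after the data were seen. The counts of 103 higher and 36 lower genes stayed within 1.5 times in 11 settings of scaling, filter, pseudocount, edgeR, limma-voom and a 2-fold minimum, from 71 to 140 higher and from 27 to 43 lower. They moved to 729 and 494 with DESeq2, 2557 and 2275 with library weights and 767 and 404 with GC and length correction. Leaving out 1 library gave 0 to 2359 higher and 0 to 2077 lower genes, and the high ends came without control replicate 3. Without it, edgeR called 2395 and 2042, DESeq2 2273 and 1924, library totals alone 2956 and 1330, and GC and length correction 2871 and 2898. An adjusted p under 0.01 in limma left 0 and 0 of the 2352 genes at an unadjusted p under 0.05. A limma test against a 1.5-fold change left 6 higher (NR1D1, TNFAIP3, ANKRD1, PTX3, ICAM1, IRAK2) and 2 lower (NR4A2, NR4A3), since it asks for a larger change. With the replicate number as a block, limma called 0 and 0 (1563 at an unadjusted p under 0.05) and edgeR 0 and 0 (1371), while 12 lists were still called. The deviations of Caba-780 and control libraries correlated at 0.303, −0.334 and −0.101 for numbers 1 to 3, and not every library correlated best with its own number. Control replicates 1 and 2 gave alike values, and control replicate 3 the opposite sign (0.303, 0.265 and −0.302 with Caba-780 replicate 1). The outlying control replicate 3 sets these deviations, so the test could not decide whether replicates of the same number were paired. No named gene changed direction in any setting. Of the 29, BMF, COX7C, NDUFB3, RPL27 and RPL5 were not called in the main fit. Each fit without control replicate 1 or 2 or a Caba-780 library lost the call of 23 or 24 of the others. Only NR1D1 kept its call, without control replicate 1. Leaving off the low-count filter lost CCNE1, CDC6, HIST1H2AC and H1F0. Library totals lost PLK1, HIST1H2AC and H1F0, and TMM scaling in limma lost HIST1H2AC and H1F0. The edgeR test with TMM and a pseudocount of 0.5 each lost H1F0, limma-voom lost HSPA6 and EGR3, and GC and length correction lost TRIB3. Of 27 lists, 12 were called with camera, 0 with an estimated correlation (lowest limma adjusted p 0.263), 0 without control replicate 3 and with an estimated correlation (0.167), and 7 with fry, which does not compare a list with other genes. The lists called with fry were mitosis, DNA replication, ATF4, NF-kB, interferon response, apoptosis regulators and ferroptosis. Other settings called 8 to 14 lists. The mitochondrially encoded mRNA list turned upward, with no call, under GC and length correction without control replicate 3 (limma camera adjusted p 0.881), against a range of 0.0605 to 0.991 in its downward alternatives that lost the call. Medians, means and tests differed in sign for unfolded protein response genes and tubulins with 6 libraries, and for mitochondrial mRNAs, drug efflux, ribosome biogenesis and luminal genes without control replicate 3. Unless named, the cause was not tested. DESeq2 size factors were not run for the lists, because the deposited values already carry size factors, and the planned limma test on normalized values is the main test. In control replicate 3, 71.7% of genes with 5 to 10 reads in the other controls had none, so that library can strongly move the folds of genes at that depth, as for ITGAM (3.37 with it and 2.24 without).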

Other observations

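The circadian clock list, the tests of few starting molecules and the tests on mitochondrial rRNA were chosen after the result was seen. Besides NR1D1, 2 other genes of the circadian clock passed the test with 6 libraries. PER2, a clock repressor, rose from 133 ± 29.8 to 568 ± 25.1 normalized counts (n = 3 per group, change 2.11 ± 0.23 SE, limma adjusted p = 0.0246), and BHLHE41 rose by 1.86 (0.0384). Of 16 clock genes tested, 3 rose and none fell with 6 libraries, and 10 rose and 2 fell without control replicate 3. PER1 (1.39), NR1D2 (1.15) and CRY1 (0.94) passed only without that library, and were also higher, short of the threshold, with 6 libraries (2.00, 0.65 and 1.08). For NR1D2, control replicate 3 (1516 normalized counts) lay above all Caba-780 libraries (1079 to 1414), and the limma adjusted p with 6 libraries was 0.487. BHLHE40 (−1.03, and −0.65 with 6 libraries) and DBP (−1.04) fell without control replicate 3. The direction of DBP turned with that library, which had 0 reads of DBP (1.49 with 6 libraries, not called). As a hypothesis, the clock genes may have risen together: the limma camera adjusted p was 7.55e-06 with 6 libraries and 0.000214 without control replicate 3, with an adjusted p = 0.239 and an adjusted p = 0.295 with an estimated correlation. The list was written because NR1D1 had been seen, so the test is not independent of it. The labels do not give the time of harvest.

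NR4A1, the remaining member of the NR4A family, had 2299 and 2757 normalized counts in control replicates 1 and 2, 291 in control replicate 3 and 185 to 303 with Caba-780. It passed without control replicate 3 (change −3.52 ± 0.19) and not with 6 libraries (−2.49 ± 0.85, limma adjusted p = 0.231). The same held for the helicase gene PIF1 (−4.38 without that library and −3.48 with it), the growth regulator ID1 (−2.35 and −1.86) and CSF1, the macrophage growth factor (3.25 and 5.51), and the difference between these fits was not tested. HSPA6 rose while the chaperone genes HSPA8 (−0.42), HSPA1A (−0.44) and HSP90AA1 (−0.40) fell without control replicate 3. ANKRD1 rose by 4.53 in the same comparison, and CTGF (−1.36) and CYR61 (−1.34), which like ANKRD1 are known targets of YAP, fell.

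Control replicate 3 differed in the number of genes with reads. Its explanation as a treated library under a control label was tested by the slope of its shift on the treated shift over 225 genes, which was 0.218 (95% bootstrap interval 0.119 to 0.323), where a treated library would lie near 1. Too few starting molecules, each read many times, is a candidate explanation: the share of genes at 0 implied 19.5 to 32.8 reads per molecule in bins from 5 to 100 reads, a ratio of 1.68, although the value rose to 76.1 in the highest bin. A bias in GC content or length may also contribute, since both together explained 63.1% of the variance of its log ratio to the other controls, and the share at 0 in genes of 20 to 50 reads was 15.7%, 33.7% and 58.3% in genes of low, middle and high GC content (equal groups). The share of variance was 25.4% to 68.6% for the other libraries, so it is the size of the shift (SD of the log2 ratio 1.04, against 0.21 between the other controls) that sets this library apart, and both explanations stay open.

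Both mitochondrial rRNAs were higher without control replicate 3, MT-RNR1 by 1.47 ± 0.14 and MT-RNR2 by 1.99 ± 0.14, and neither passed with 6 libraries (limma adjusted p = 0.206 and 0.261). More mitochondrial RNA as a whole argues for a like rise of the mRNAs, but the smaller rRNA change lay 1.45 above the median of the 13 mitochondrial mRNAs (SD 0.55). More carry-over of RNA without a poly(A) tail would raise small nuclear and nucleolar RNAs, whose summed reads were 0.889 times those of control replicates 1 and 2, but the labels do not say whether RNA was poly(A) selected, and the test bears only on libraries that were. MT-RNR2 had 55891 normalized counts in control replicate 3, as high as the 53908 to 71759 with Caba-780 and above the 14799 and 15705 of the other controls. A difference between library preparations, rRNA removal included, therefore could be involved as well as the treatment, and this was not tested.

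The fall of ribosomal protein and respiratory chain genes without control replicate 3 was tested for a bias in GC content or gene length. Length was the deposited bases per gene, with medians of 3667 (ribosomal) and 3151 (respiratory), against 4849.5 for all tested genes. After each library was corrected for a trend over both, the medians kept 95.7% (ribosomal) and 92.1% (respiratory) of their size. The limma camera adjusted p values were then 2.56e-05 and 0.000141. This argues against a trend over GC content and that length as the whole cause. The deposited length need not be that of the mature mRNA, so the test could not decide on a bias in mRNA length. The camera calls of both lists rest on the preset correlation. The treatment remains an open, biological explanation.

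Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split called 139 genes and 1 of 10 splits reached that number, with 0 as the highest of the others. For lists the real split called 12 and 1 of 10 splits reached that number, with 7 as the highest of the others.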
